A study of Mus musculus with 24 samples.

How the data were processed

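The study measured total RNA from the number 4 inguinal mammary gland, lymph node removed, of C57BL/6 females. The 4 groups were wild-type virgins (n = 7), virgins homozygous for the SOCS2 R96C knock-in allele (n = 7), wild-type mice at pregnancy day 18 (n = 5) and knock-in mice at that day (n = 5). Per the labels, tissue was frozen in liquid nitrogen, RNA was extracted with RNA NOW, and Cy3-labelled cRNA was made with the One-Color Low Input Quick Amp kit and hybridized to 60K mouse arrays. Animal numbers in the labels are all different, so the groups are unpaired, and 24 animals on 3 slides of 8 arrays were analysed.

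Per the file headers, the authors scanned 1 colour channel and extracted signals with Agilent Feature Extraction 12.0.3.2 under protocol GE1_1200_Jun14. The deposited text files hold each spot's processed signal, mean and median signal and local background in units of intensity (scanner brightness), with quality calls of 0 or 1. The processed signal is background-subtracted and detrended within the array, with a surrogate value near background and no scaling between arrays. The deposited series matrix holds log10 of the processed signal for 62969 features. Its smallest correlation with log10 of the signal in the text files was 1.0000, with a slope of 1.000 and a largest difference of 0.0050. How the authors scaled arrays against each other for their own tests is not given in the sources used here.

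Each array has 62976 spots, of which 59305 are not controls; they belong to 56605 probes, and 300 probes have 10 replicate spots each. Between 33374 and 57003 spots per array were well above background, and 0 non-control spots were saturated. By group the range was 37504 to 38814 in wild-type virgins, 36168 to 57003 in knock-in virgins, 33413 to 37886 in wild-type pregnant and 33374 to 43055 in knock-in pregnant mice. Of the probes, 35405 took their gene name from their accession in the RefSeq table given, 9124 from a current symbol and 25 from a synonym, and 12051 kept the name in the file; 26 names changed. Probe coordinates are those in the files, on mm9, and were used only for distances between Socs2 probes.

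Spots that the scanner software marked as outliers were set to missing, and replicate spots were averaged on the log2 scale. Processed signals were set to log2 and each array's 75th percentile was subtracted. A probe was kept if well above background on at least 80% of the arrays of at least 1 group, which left 35117 probes. For the 8109 genes with several probes, the probe of the highest mean over all arrays stood for the gene, giving 22382 genes with 162 missing values. There were 90 genes in wild-type and 80 in knock-in mice with probes called in opposite directions between stages.

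Models were fitted with limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table. A mean per group was fitted to all 24 arrays, with moderated statistics and Benjamini-Hochberg adjustment over all genes of a comparison. A gene was called at an adjusted p under 0.05. The 6 comparisons were the genotype effect in virgins, the genotype effect at day 18, their difference, their average, and the stage effect in each genotype. Median standard errors of log2 differences were 0.24, 0.29, 0.38 and 0.19 for the genotype comparisons in that order. Errors after ± are standard errors unless marked SD. A further test adjusted p values over the list alone. Exact p values came from all 3432 splits of the virgins or all 252 splits of the pregnant mice. Across-gene correlations treat genes that are not independent replicates.

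There were 32 gene lists, covering milk secretion, lipid synthesis, hormone signalling, epithelial, stromal, immune, muscle, nerve, skin and blood cells, and general functions. Lists, comparisons, the rule for naming genes and most alternatives were fixed before the data were examined. Lists were tested against all other genes on moderated statistics, by the computation of limma's camera, with a preset correlation of 0.01 among members. The test was repeated with a correlation estimated from the data, which ranged from 0.01 to 0.89, with missing values replaced by the group mean. List p values were adjusted over the 32 lists of a comparison. List scores are the mean log2 value over members on each array.

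Genes were named by a rule: Socs2 everywhere, the largest rises and falls that passed or else the smallest p values, and members of each list. The rule took 905 gene-by-comparison entries on 389 genes. The text gives 147 of them, the examples within lists being chosen after their values were seen, and leaves out 758. Where a gene was well above background on no array of the dim group, or in a stage comparison on under 50% of them, only a lower bound of its fold change is given. The second case was added after the values were seen. A gene counted as well above background on an array if any of its probes was, so such counts need not describe the probe that gave its fold.

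Alternatives fixed beforehand were median scaling, quantile normalization, scaling to 7 spike-in probes, normexp background correction with an offset of 50, median signal without background subtraction, the deposited series matrix, no filter on dim probes, only probes bright on all arrays, outlier spots kept, slide as a fixed or random block, each slide alone, trended and robust moderation, array weights, each array left out in turn, the mean of a gene's probes, every probe alone, only the 2 groups compared, an adjusted p under 0.01 and a 2-fold limit. After the data were seen, 3 were added: without the arrays of mice 376 and 184, without those and mouse 198, and with luminal and muscle scores as covariates. Values of luminal and muscle genes and lists under that covariate were left out, since the covariate is built from them; this was decided after they were seen. For the luminal and milk lists, a test without mice 376 and 198 was replaced, after its values were seen, by one also without wild-type virgin 317, since mouse 198 had been singled out by its luminal score. The limit for deciding that test was then made stricter by 1 standard error. The consensus correlation of arrays on a slide was −0.042.

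The animals were regrouped in 100 ways including the real one: genotype within stage for genotype comparisons, stage within genotype for stage comparisons. The code was tested on simulated data of 22382 genes with 200 changed in each comparison. For 1.5-, 2-, 4- and 8-fold changes it recovered 18%, 54%, 86% and 96% in the virgin comparison and 4%, 20%, 72% and 94% at day 18, with 7 and 4 false calls. A list of T cell genes moved by 1 log2 unit was recovered with adjusted p = 6.67e-37 and 0 other lists. The simulated noise was independent between genes, without deviations shared over an array. With 200 genes changed at once, the adjusted threshold was also easier to pass than with few changed genes. These tests can therefore overstate recovery, and they do not show how often lists pass by chance on the real arrays. Over the 100 regroupings the median number of lists past the preset test was 13 in virgins, 10 at day 18 and 12 in each other comparison. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9. Control spots were left out of all tests; no array was left out of the values given unless stated.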

Results

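Number 4 inguinal mammary glands, with the lymph node removed, came from C57BL/6 females that were wild type or homozygous for the SOCS2 R96C knock-in allele. Total RNA was measured on 1-colour mouse arrays. There were 7 wild-type and 7 knock-in virgins at 8 weeks, and 5 wild-type and 5 knock-in mice at pregnancy day 18. The age of the day-18 mice is not given in the labels used here, so effects of pregnancy and of age cannot be told apart. The 24 animals were distinct, and each of the 3 slides held 8 arrays with all 4 groups among them. Slide 1 holds 1 wild-type day-18 array and slide 3 holds 1 knock-in day-18 array, so values within these slides that use them rest on 1 animal in that group. SOCS2 is a feedback inhibitor of growth hormone, prolactin and STAT5 signalling. An expression array does not read a single-base change, so the genotypes rest on the labels.

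After filtering, 22382 genes were tested. Values are log2 signals relative to each array's 75th percentile, and each fold change is followed by its standard error and an adjusted p. One knock-in virgin array, from mouse 376, had a negative-control signal of 332 against 19.4 to 41.4 on the other 23 arrays, and 57003 of 59305 spots counted as well above background. A knock-in pregnant array, from mouse 184, gave 43055 such spots. Knock-in virgin 198 had the lowest luminal marker score, −3.30 against 0.41 for the nearest array of its group, and the highest skeletal muscle score, 6.27 against 0.48. These 3 arrays were kept, and counts of calls and several lists are also given without some or all of them. The scanner software also marked knock-in virgins 196, 314 and 251 and wild-type pregnant 233, with 1 quality metric out of range each, and these were kept.

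Does the knock-in allele alter its own transcript? The array holds 4 probes named Socs2, all well above background on every array, and they behaved in 2 ways. The brighter of 2 probes annotated to the curated reference transcript had a mean of 1.58 ± 0.96 (SD) in 7 wild-type virgins and 0.99 ± 0.74 in 7 knock-in virgins, a difference of −0.60 ± 0.35 (adjusted p = 0.702). At day 18 it had 1.32 ± 0.30 and 1.37 ± 0.22 in 5 animals each, a difference of 0.05 ± 0.42 (adjusted p = 1.00). A second probe annotated to that transcript, 402 bp away, had differences of −0.66 and −0.09 (exact p = 0.191 and exact p = 0.706).

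The other pair of Socs2 probes, lying 24721 and 27463 bp from that second probe on the mm9 assembly and annotated to other Socs2 transcripts, read higher in knock-in glands. The farther one had −2.70 ± 0.72 (SD) in wild-type and −1.13 ± 0.66 in knock-in virgins (adjusted p = 0.441 over all probes), and −3.43 ± 0.23 and −1.45 ± 0.07 at day 18 (adjusted p = 0.179). Its pregnant knock-in values, −1.54 to −1.37, did not overlap the wild-type values, −3.66 to −3.10. Averaged over stages it passed, with a difference of 1.78 ± 0.22 (adjusted p = 0.0013 over 35117 probes), and so did the nearer distal probe, with 1.60 ± 0.25 (adjusted p = 0.0210). Exact p were 0.0012 in virgins and 0.0079 at day 18 for the farther probe, and exact p were 0.0029 and 0.0079 for the nearer. Within slides 1, 2 and 3 the farther probe differed by 1.62, 1.38 and 1.94 in virgins and by 2.17, 2.16 and 1.71 at day 18. The 16 measured neighbours of Socs2 on its chromosome had a median averaged genotype difference of −0.11. Because the gene-level value follows the brightest probe, Socs2 as a gene did not pass in any of the 6 comparisons, and the plot of the 4 probes shows both behaviours.

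**Figure D1:**
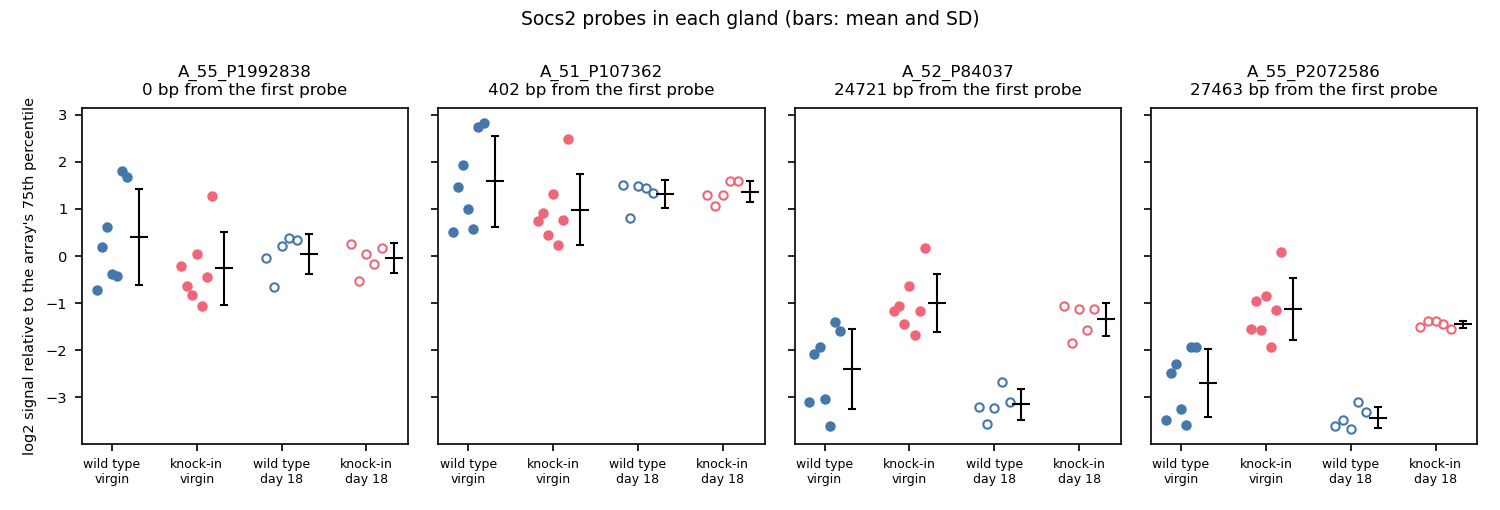
Signal of each of the 4 Socs2 probes on every array, by genotype and stage, as log2 relative to the array's 75th percentile. Panels give each probe's distance in bp from the probe of the highest coordinate.

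What does pregnancy change in the wild-type gland? Milk protein genes were among those that rose most. Csn1s2b, a calcium-sensitive casein, rose 1400-fold (log2 10.45 ± 0.75, adjusted p = 3.94e-10), Wap, whey acidic protein, 1037-fold (10.02 ± 1.56, adjusted p = 1.93e-05), and Csn1s1, alpha casein, 855-fold (9.74 ± 1.28, adjusted p = 2.43e-06), each with 5 day-18 against 7 virgin glands. Csn2, beta casein, rose 518-fold (9.02 ± 1.53, adjusted p = 5.46e-05) and Lalba, the alpha-lactalbumin of lactose synthase, 398-fold (8.64 ± 0.59, adjusted p = 1.55e-10). Elf5, the transcription factor of alveolar fate, rose 47.1-fold (5.56 ± 0.80, adjusted p = 7.25e-06). On the falling side, Areg, the amphiregulin of oestrogen-driven duct growth, fell at least 134-fold (adjusted p = 1.45e-07; 1 of 5 day-18 arrays), and Pgr, the progesterone receptor, 9.64-fold (−3.27 ± 0.54, adjusted p = 3.79e-05).

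In wild-type glands 4686 genes were higher and 4671 lower at day 18, 41.8% of those tested, and 2215 of them changed at least 4-fold (1064 higher, 1151 lower). Leaving out the arrays of mice 376 and 184 raised the count to 13271. Both are knock-in mice, so the wild-type means were unchanged, and the rise came through the estimate of spread that the 4 groups share. Whether a gene was called in wild-type mice thus depends in part on these arrays. None of 99 other splits of the animals exceeded 15 genes, so chance can be excluded for the count of 9357. The directions are relative to the 75th percentile of each array. Scaled to 7 spike-in probes, the median of all genes moved by −0.92 and 1142 genes were higher against 13665 lower. With normexp background correction the median moved by 0.13 and 59.5% of called genes were higher, and with median scaling it moved by 0.18.

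The largest increases went beyond the caseins. Lao1, an L-amino acid oxidase of milk, rose 2634-fold (11.36 ± 1.00, adjusted p = 7.72e-09), Olah, the thioesterase that releases medium-chain fatty acids, 2577-fold (11.33 ± 1.00, adjusted p = 8.35e-09), and Saa2, an acute-phase serum amyloid, 1880-fold (10.88 ± 0.85, adjusted p = 1.44e-09). Chrdl2, a secreted BMP antagonist, rose 1589-fold (10.63 ± 0.90, adjusted p = 4.87e-09), Sycn, a secretory granule protein, at least 749-fold (adjusted p = 3.64e-09), and Drd4, a dopamine receptor, at least 335-fold (adjusted p = 2.69e-09). These genes were dim in virgins: Lao1, Saa2, Csn1s2b, Wap and Csn2 were well above background on 5 of 7 wild-type virgin arrays, Olah and Csn1s1 on 6, Chrdl2 on 4, and Sycn and Drd4 on 1. Spp1, osteopontin, rose 667-fold (9.38 ± 0.37, adjusted p = 1.52e-14) and Saa1 184-fold (7.53, adjusted p = 4.50e-12).

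Where a gene was well above background on under 50% of the arrays of 1 stage, only a bound is given, as for Areg, Sycn and Drd4. The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the dim probe's own signal and the lowest signal among probes well above background. Atp13a4, a cation-transporting ATPase, rose at least 319-fold (adjusted p = 7.92e-09). Dmbt1, a mucosal scavenger-receptor glycoprotein, fell at least 1608-fold (adjusted p = 1.05e-09). Falls of at least 79.3-fold were found for Fam25c (adjusted p = 2.18e-07), 35.9-fold for Cyp3a57, a cytochrome P450 (adjusted p = 8.59e-06), 32.9-fold for Sprr1a, a cornified envelope protein (adjusted p = 6.72e-06), 26.3-fold for Abcc8, the sulphonylurea receptor (adjusted p = 9.29e-10), 16.9-fold for R3hdml (adjusted p = 4.49e-06), 16.8-fold for Fgb, fibrinogen beta (adjusted p = 5.63e-04), and 10.6-fold for Ucp1, the brown fat uncoupling protein (adjusted p = 0.0074). Ido1, the tryptophan-degrading dioxygenase, fell at least 273-fold (adjusted p = 4.81e-07) and was measured on 1 of 5 day-18 arrays. Ptn, the growth factor pleiotrophin, fell 57.9-fold (−5.86 ± 0.59, adjusted p = 5.87e-08).

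Gene lists fixed before the data were examined followed the same lines. Of 30 milk protein and secretion genes, 28 rose and 2 were not called (median 5.70, adjusted p = 3.94e-19; adjusted p = 0.0151 with an estimated correlation, and adjusted p = 0.210 so estimated without the arrays of mice 376 and 184). No other list kept its call with an estimated correlation. In the luminal epithelium list 15 of 25 genes rose and none fell (median 1.88, adjusted p = 1.34e-04, and adjusted p = 0.747 with an estimated correlation). Among them was Cd14, a lipopolysaccharide receptor (10.3-fold, adjusted p = 4.43e-09). Esrp1, an epithelial splicing factor, rose 10.0-fold (3.32 ± 0.40, adjusted p = 6.80e-07). Krt18, a luminal keratin, had 0.37 (adjusted p = 0.743). The basal and myoepithelial list had 13 genes higher, 2 lower and 9 not called (median 1.21, adjusted p = 6.11e-04; adjusted p = 0.741 with an estimated correlation). Acta2, smooth muscle actin, rose 5.28-fold (2.40 ± 0.40, adjusted p = 4.53e-05) and Mylk, myosin light chain kinase, 4.70-fold (2.23 ± 0.22, adjusted p = 4.89e-08), while Krt14, the basal keratin, had 1.60 (adjusted p = 0.0642; adjusted p = 0.0371 with slide as a block).

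Hormone-sensing luminal markers mostly went the other way, with 13 of 19 lower and 1 higher, the coactivator Cited4 at 4.59 (list median −2.11, adjusted p = 4.35e-04, and adjusted p = 0.654 with an estimated correlation). Scaled to the spike-ins, where most genes fall, the median was −3.03 and the list call ended. Esr1, the oestrogen receptor, fell 4.39-fold (−2.14 ± 0.29, adjusted p = 4.46e-06), and Prlr, the prolactin receptor, had −1.47 (adjusted p = 0.0955). Within the STAT5 target and SOCS feedback list 7 genes rose, 4 fell and 9 were not called (median 0.07, adjusted p = 0.390). Cish, a STAT5-induced feedback inhibitor, rose 5.28-fold (2.40 ± 0.49, adjusted p = 3.67e-04), Stat5a 1.99-fold (0.99 ± 0.27, adjusted p = 0.0043), and Socs1, a JAK inhibitor, fell 3.59-fold (−1.84 ± 0.26, adjusted p = 5.08e-06). Socs3 (0.06, adjusted p = 0.895), Stat5b (0.54, adjusted p = 0.114) and Jak2 (−0.30, adjusted p = 0.429) were not called. Among growth hormone and IGF genes 5 rose and 9 fell (median −0.55, adjusted p = 0.183), with Igf1 lower by 6.91-fold (−2.79 ± 0.25, adjusted p = 1.05e-08) and Ghr, the growth hormone receptor, by 3.05-fold (−1.61 ± 0.33, adjusted p = 3.99e-04).

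Stromal and fat markers fell. In the fibroblast and matrix list 21 of 24 were lower and none higher (median −1.69, adjusted p = 1.39e-08; adjusted p = 0.654 with an estimated correlation), including Fn1, fibronectin (7.82-fold, adjusted p = 3.05e-06), and Col5a2, a fibrillar collagen chain (4.62-fold, adjusted p = 4.24e-07). White adipocyte genes had 17 of 28 lower (median −1.56, adjusted p = 1.88e-05; adjusted p = 0.741 with an estimated correlation). Plin1, which coats lipid droplets, fell 6.26-fold (−2.65 ± 0.35, adjusted p = 2.59e-06) and Adipoq, the adipokine adiponectin, 3.49-fold (−1.80 ± 0.38, adjusted p = 5.42e-04). Lep, leptin, had 0.13 (adjusted p = 0.611). Endothelial genes had 10 of 21 lower and 1 higher (median −0.54, adjusted p = 0.0039; adjusted p = 0.741 with an estimated correlation), a call that ended with median scaling (−0.36). Vwf, von Willebrand factor, fell 2.84-fold (adjusted p = 1.73e-05), while Prox1, a lymphatic regulator, rose 11.8-fold (adjusted p = 7.89e-06; 6 of 7 virgin arrays).

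Macrophage and monocyte genes had 16 of 23 lower and 2 higher (median −1.29, adjusted p = 0.0021; adjusted p = 0.747 with an estimated correlation), with Mrc1, the mannose receptor, down 4.44-fold (adjusted p = 3.59e-05). The mast cell and eosinophil list had 11 of 17 lower (median −1.49, adjusted p = 0.0021; adjusted p = 0.741 with an estimated correlation), with Gata2, a mast cell factor, down 2.80-fold (adjusted p = 2.00e-07). Of 30 interferon-response genes 17 fell and none rose (median −1.15, adjusted p = 2.13e-04; adjusted p = 0.747 with an estimated correlation), among them Oas2, a viral RNA sensor, down 4.24-fold (adjusted p = 1.30e-04). Nerve and Schwann cell genes had 8 of 13 lower and 1 higher (median −1.84, adjusted p = 0.0039; adjusted p = 0.654 with an estimated correlation). S100b, a Schwann cell calcium-binding protein, fell 10.4-fold (adjusted p = 3.35e-08), and Sox10, a neural crest factor also known in mammary epithelium, rose 8.73-fold (adjusted p = 3.31e-07). Red blood cell genes had 8 of 9 lower (median −1.58, adjusted p = 8.68e-04; adjusted p = 0.654 with an estimated correlation), with Hbb-b2, a beta globin, down 3.99-fold (adjusted p = 8.81e-04). Scaled to the spike-ins the macrophage (−2.21), mast cell (−2.41) and nerve calls (−2.76) ended, and with luminal and muscle scores as covariates the macrophage and basal calls did.

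Cell cycle and ribosomal lists rose. Cell cycle genes had 17 of 32 higher and none lower (median 1.23, adjusted p = 6.11e-04; adjusted p = 0.747 with an estimated correlation), with Mki67, a proliferation antigen, up 4.00-fold (adjusted p = 0.0031) and Cdk1, the mitotic kinase, 3.63-fold (adjusted p = 0.0034). Ribosomal protein genes had 74 of 80 higher and 2 lower (median 0.95, adjusted p = 7.80e-13; adjusted p = 0.741 with an estimated correlation), and Rpl22l1 rose 2.76-fold (adjusted p = 3.75e-05). Scaled to the spike-ins, the ribosomal median was 0.03. Endoplasmic reticulum chaperones had 9 of 25 higher (median 0.24, and −0.68 scaled to the spike-ins; adjusted p = 0.0244; adjusted p = 0.747 with an estimated correlation), a call that ended with quantile normalization, median or spike-in scaling, normexp correction, median signal, bright probes only and array weights, and, for the endoplasmic reticulum chaperones, without mouse 376 (0.24), 233 (0.18) or 206 (0.21). Xbp1, the secretory stress factor, rose 4.21-fold (adjusted p = 1.74e-07).

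The remaining lists were not called. Milk lipid synthesis split into 8 higher and 7 lower of 28 (median −0.12, mean 0.76, adjusted p = 0.362), although Fads1, a fatty acid desaturase, rose 7.07-fold (2.82 ± 0.21, adjusted p = 6.10e-10). Cholesterol synthesis had a median of −0.04 and a mean of 0.08 (adjusted p = 0.917), brown and beige adipocyte genes −0.93 (adjusted p = 0.362), T cells 0.48 (adjusted p = 0.0536), B cells and plasma cells −0.31 (adjusted p = 0.793), lymph node stroma −0.31 (adjusted p = 0.958), and neutrophils −0.05 (adjusted p = 0.958). Inflammatory cytokines and acute-phase genes had 0.32 (adjusted p = 0.254), immediate early genes 0.02 with a mean of −0.24 (adjusted p = 0.917), glucose and lactose metabolism 0.28 (adjusted p = 0.115), skeletal muscle −1.78 (adjusted p = 0.346), and skin and hair 0.38 (adjusted p = 0.348). Socs2 neighbours had −0.11 (adjusted p = 0.735), C57BL/6 substrain genes 0.08 (adjusted p = 0.958), and oxidative phosphorylation 0.15 (adjusted p = 0.369). For the B cell, lymph node stroma and neutrophil lists too, the median, the mean and the test did not share 1 sign. Oxidative phosphorylation turned to −0.49 with quantile normalization (adjusted p = 3.14e-08 by the preset test) and with median signal (adjusted p = 4.12e-08).

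With slide as a block Csn2 had 8.97, and within slides 1, 2 and 3 it had 10.15, 6.33 and 10.07. Wap had 10.00, then 10.57, 7.51 and 11.34, and Igf1 −2.80, then −2.99, −2.90 and −2.56. The milk list had 5.78, then 5.35, 6.20 and 5.17, the luminal list 2.01, then 1.71, 2.49 and 1.59, and the white adipocyte list −1.57, then −1.07, −1.45 and −1.60. All 15 lists past the threshold, and 59 of 63 genes compared this way, kept 1 direction in every slide. Socs2, Krt18, Socs3 and Lep did not.

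Does the knock-in gland make the same change? In knock-in mice Wap rose 10577-fold (13.37 ± 1.56, adjusted p = 4.22e-07), Csn1s1 at least 6935-fold (adjusted p = 3.99e-08) and Csn2 3124-fold (11.61 ± 1.53, adjusted p = 2.22e-06), with 5 day-18 against 7 virgin glands. Lalba rose 524-fold (9.03 ± 0.59, adjusted p = 7.60e-11). Elf5 rose 104-fold (6.70 ± 0.80, adjusted p = 5.59e-07), and Igf1 fell 3.92-fold (−1.97 ± 0.25, adjusted p = 1.30e-06). In the virgin knock-in glands Wap was well above background on 4 of 7 arrays, Csn1s1 on 3 and Elf5 on 6, so the size of these folds depends on signals near background.

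There were 5117 genes higher and 4541 lower, 43.2% of those tested, and 2188 changed at least 4-fold. Of the genes called in wild-type mice, 7962 were called in the same direction in knock-in mice and 0 in the opposite one. The stage effects of the genotypes correlated at 0.950 across genes, which are not independent replicates, and the plot of 1 genotype against the other shows them along the diagonal. Without the arrays of mice 376 and 184 the count was 12453. None of 99 other splits exceeded the count of 9658. The highest, 2503 genes, came from a split that left 2 of 12 knock-in arrays with their real stage, and so largely exchanged the stages. Scaled to the spike-ins, the median moved by −0.83 and 10.5% of called genes were higher; with normexp correction 61.5% were, and with median scaling the median moved by 0.20.

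**Figure D2:**
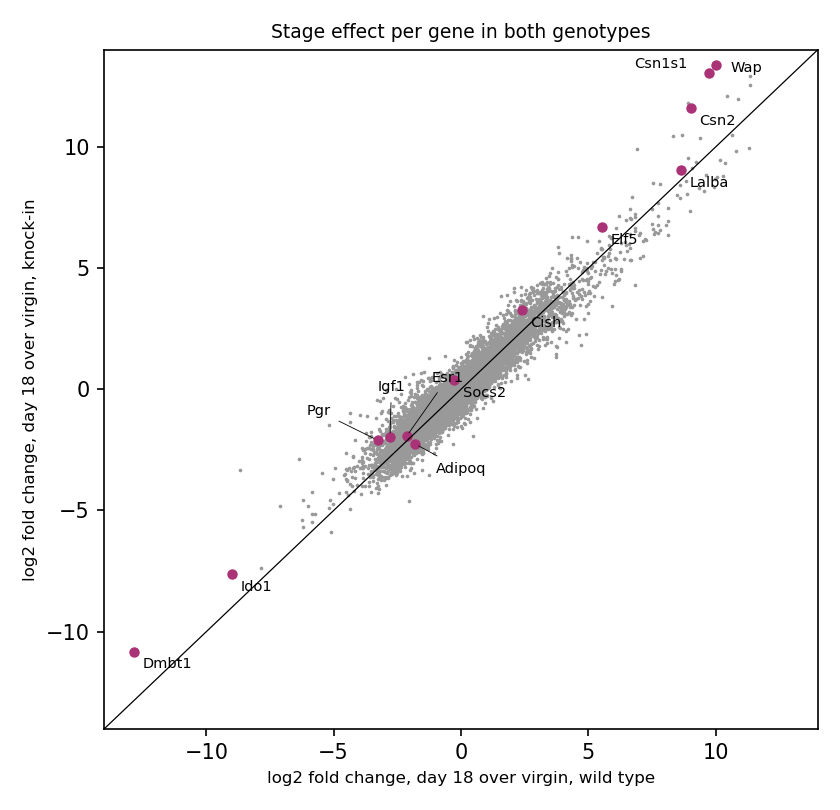
Log2 fold change from virgin to day 18 for each gene, in wild-type mice (horizontal) and knock-in mice (vertical), with the line of equal change. Values are fitted and include genes near or below background, such as Dmbt1 and Ido1 at day 18, for which the text gives bounds.

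Other large increases in knock-in mice were those of Lao1 (at least 5728-fold, adjusted p = 9.89e-10; 3 of 7 virgin arrays), Olah (6028-fold, adjusted p = 1.66e-09; 4 of 7), Csn1s2b (4393-fold, adjusted p = 3.35e-11; 5 of 7), Saa2 (3994-fold, adjusted p = 2.68e-10; 5 of 7) and Csn1s2a (3581-fold, adjusted p = 4.98e-06; 6 of 7). Sftpd, a collectin of mucosal surfaces, rose at least 1590-fold (adjusted p = 2.35e-07; 3 of 7) and Gjb6, a gap junction protein, at least 532-fold (adjusted p = 9.47e-09; 2 of 7). Dmbt1 fell at least 399-fold (adjusted p = 1.31e-08), Ido1 at least 78.3-fold (adjusted p = 3.78e-06) and Gap43, a growth cone protein, at least 10.7-fold (adjusted p = 5.01e-09). Fam25c fell at least 59.1-fold (adjusted p = 4.81e-07), Crym, a thyroid hormone-binding crystallin, at least 29.3-fold (adjusted p = 9.58e-08), and Abcc8 at least 16.4-fold (adjusted p = 3.40e-09), each measured on 1 of 5 day-18 arrays. Ptn fell 45.1-fold (adjusted p = 1.41e-07), Pon1, paraoxonase, 30.6-fold (adjusted p = 1.23e-07), Acsm3, a medium-chain acyl-CoA synthetase, 24.2-fold (adjusted p = 4.78e-07), and Lncbate1, a brown fat non-coding RNA, 19.5-fold (adjusted p = 2.63e-09), the last 3 measured on 4 of 5 day-18 arrays.

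Among STAT5-linked genes, Cish rose 9.66-fold (3.27 ± 0.49, adjusted p = 1.09e-05), Stat5a 2.70-fold (1.43 ± 0.27, adjusted p = 1.41e-04) and Socs3 1.97-fold (0.98 ± 0.27, adjusted p = 0.0044). Krt14 rose 6.03-fold (2.59 ± 0.68, adjusted p = 0.0035), but with luminal and muscle scores as covariates Krt14 had −0.70 (adjusted p = 0.224). Plin1 fell 7.52-fold (−2.91 ± 0.35, adjusted p = 6.46e-07), Adipoq 4.77-fold (−2.25 ± 0.38, adjusted p = 4.90e-05), Esr1 3.83-fold (−1.94 ± 0.29, adjusted p = 1.38e-05) and Pgr 4.29-fold (−2.10 ± 0.54, adjusted p = 0.0028).

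All 30 milk genes rose (median 6.36, adjusted p = 2.08e-21; adjusted p = 0.0086 with an estimated correlation, and adjusted p = 0.119 so estimated without the arrays of mice 376 and 184). The other 15 lists past the threshold lost their call with an estimated correlation. At adjusted p = 0.559 with an estimated correlation stood luminal epithelium (18 of 25 higher, none lower; median 2.57, adjusted p = 1.27e-07), basal (18 of 24 higher; median 1.30, adjusted p = 2.26e-04), hormone-sensing (10 of 19 lower; median −1.74, adjusted p = 0.0124) and white adipocyte genes (20 of 28 lower; median −1.75, adjusted p = 1.25e-07). So did fibroblast (21 of 24 lower; median −1.56, adjusted p = 9.25e-09), endothelial (14 of 21 lower; median −0.74, adjusted p = 3.53e-04), mast cell and eosinophil (11 of 17 lower; median −1.83, adjusted p = 7.09e-04), nerve (7 of 13 lower; median −1.0, adjusted p = 0.0335) and inflammatory genes (12 of 27 higher, 7 lower; median 0.64, and −0.19 scaled to the spike-ins; adjusted p = 0.0201), a call that ended with quantile normalization.

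At adjusted p = 0.818 with an estimated correlation stood macrophage (16 of 23 lower, median −1.19, adjusted p = 0.0155), interferon-response (11 of 30 lower, median −0.70, adjusted p = 0.0176) and cell cycle genes (11 of 32 higher, median 0.90, adjusted p = 0.0101). Spike-in scaling moved the median of all genes by −0.83, a shift that takes away most of the cell cycle rise. Ribosomal protein genes had 76 of 80 higher (median 1.09, and 0.26 scaled to the spike-ins; adjusted p = 3.20e-14; adjusted p = 0.599 with an estimated correlation), and red blood cell genes 6 of 9 lower (median −1.04, adjusted p = 0.0176; adjusted p = 0.599 with an estimated correlation). Endoplasmic reticulum chaperones had 12 of 25 higher (median 0.44, and −0.40 scaled to the spike-ins; adjusted p = 0.0028; adjusted p = 0.637 with an estimated correlation), a call that ended with quantile normalization. Scaled to the spike-ins the hormone-sensing (−2.57), macrophage (−2.03), mast cell (−2.66), interferon (−1.53), nerve (−1.84) and red blood cell calls (−1.87) ended. With covariates the basal, macrophage, interferon, nerve and red blood cell calls ended. The nerve and Schwann cells call ended without mouse 376 (−1.14) or 384 (−0.89), the interferon response call without 251 (−0.56) or 384 (−0.53), and the cell cycle call without 239 (0.64). With slide as a block Wap had 13.26, and 11.34, 14.59 and 15.11 within slides 1, 2 and 3; the milk list had 6.41, then 5.81, 7.99 and 5.59. The chaperone list alone of the 16 changed sign, with 0.91, 0.51 and −0.05.

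What does the allele change in the virgin gland? Milk and hormone-response genes had lower means in knock-in virgins, but no gene passed, all with adjusted p = 0.702 in 7 against 7 mice. Csn1s1 had −3.28 ± 1.17, Wap −3.33 ± 1.42, Csn2 −2.56 ± 1.40 and Areg −3.10 ± 0.85. Csn1s1 was well above background on 3 of 7 knock-in arrays and Wap on 4, so the size of these 2 rests on signals near background. Igf1, the growth factor that growth hormone induces, had −0.64 ± 0.23, and the STAT5-linked Cish, Socs3 and Stat5a had −0.83 ± 0.45, −0.64 ± 0.24 and −0.50 ± 0.24. The milk genes varied by slide: Csn2 had −0.09, −6.12 and −2.85 within slides, Wap −0.88, −6.96 and −3.84, and Csn1s1 −2.31, −7.12 and −1.89. Slide 1, with mouse 376, gave the lowest values of Igf1 (−1.14, −0.45 and −0.10), Socs3 (−1.38, −0.09 and −0.29), Stat5a (−0.95, −0.26 and −0.07) and Cish (−0.85, −0.63 and −0.35). Without that mouse Igf1 had −0.41, Socs3 −0.54, Stat5a −0.32 and Cish −0.91. The largest values by test were those of Sectm1a (2.50 ± 0.54; 2 of 7 wild-type arrays), Kng1, kininogen (1.39 ± 0.34), Hoxd9, a positional homeobox factor (0.73 ± 0.18), Prag1, a pseudokinase scaffold (−1.09 ± 0.24), Sprr1a (−3.49 ± 0.83; 5 of 7 knock-in arrays) and Sik1, a cAMP-induced kinase (−1.01 ± 0.25).

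By limma 0 genes were called, 802 had an unadjusted p under 0.05 (326 higher in knock-in), and 1119 would by chance alone. Without the arrays of mice 376 and 184 the counts were 0 and 768. With array weights 21 genes were called (8 higher, 13 lower), and 2074 had an unadjusted p under 0.05. Of the 100 splits, 62 including the real one reached 802, so chance cannot be excluded. With slide as a block Areg had −2.96, and −2.71, −3.83 and −2.28 within slides, and Kng1 1.45, then 1.88, 0.85 and 1.55, all at adjusted p = 0.809. The median standard error of 0.24 limits what could be called: of simulated genes, 54% were recovered at 2-fold and 86% at 4-fold. The simulation changed 200 genes at once, up to 8-fold, with noise independent between genes, so it can overstate recovery of a lone change. Median scaling moved the median of all genes by −0.39, mainly through mouse 376. Its array had a log2 median of 10.76 and a 75th percentile of 11.67. The other virgin arrays had medians of 5.19 to 6.12 and 75th percentiles of 8.81 to 9.65.

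As lists, 17 of 32 passed the preset test and none with an estimated correlation, where the smallest was adjusted p = 0.330, and no member was called over all genes. Luminal epithelium was lowest, with a median of −0.91 (adjusted p = 2.59e-09; adjusted p = 0.412 with an estimated correlation), −0.95 with slide as a block and −0.69, −1.76 and −0.89 within slides. Milk genes had −0.65 (adjusted p = 1.33e-06; adjusted p = 0.330 with an estimated correlation), −0.67 blocked and −0.77, −1.02 and −0.66 within slides. Beside them, mouse 198 stood apart in luminal and muscle score, and the skeletal muscle list had 1.56 (adjusted p = 0.0029; adjusted p = 0.754 with an estimated correlation) and 2.06, 4.75 and −0.97 within slides. Ckm, muscle creatine kinase, had 2.92 ± 2.48.

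Immediate early genes, which respond to stimulation and to tissue handling, had a median of −0.41 (adjusted p = 8.51e-07; adjusted p = 0.330 with an estimated correlation), −0.44 blocked and −0.68, −0.36 and −0.08 within slides. Myc had −0.46 ± 0.15, Egr2 −1.0 ± 0.38 and Hspa1a, a heat shock protein, −0.58 ± 0.23. The score per animal was 1.17 ± 0.10 (SD) in wild-type and 0.75 ± 0.38 in knock-in virgins (exact p = 0.0012, or 0.0373 adjusted over the 32 lists), the only list to pass that test. Hormone-sensing genes had −0.73 (adjusted p = 2.09e-05), STAT5 targets −0.29 (adjusted p = 5.47e-04) and red blood cells, with Hbb-b2 at −1.03 ± 0.41, −0.80 (adjusted p = 3.13e-05), each with adjusted p = 0.330 with an estimated correlation. Basal genes, with Sostdc1, a BMP and WNT inhibitor, at −0.86 ± 0.23, had −0.53 (adjusted p = 5.37e-05) and chaperones −0.33 (adjusted p = 6.10e-06), each with adjusted p = 0.412 with an estimated correlation. Adjusted over the list alone, 1 hormone-sensing and 1 basal gene were lower.

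T cell genes had 0.38 (adjusted p = 2.12e-07; adjusted p = 0.349 with an estimated correlation), −0.02 with median scaling. B cell genes had 0.48 (adjusted p = 0.0014) and brown and beige adipocyte genes 0.38, or −0.01 with median scaling (adjusted p = 0.0029), each with adjusted p = 0.499 with an estimated correlation. Growth hormone and IGF genes had −0.33 (adjusted p = 0.0048; adjusted p = 0.446 with an estimated correlation). Milk lipid genes had −0.24 (adjusted p = 0.0193) and interferon-response genes −0.26 (adjusted p = 0.0144), each with adjusted p = 0.754 with an estimated correlation. Ribosomal genes, with Rpl30 at −0.34 ± 0.17, had −0.36 (adjusted p = 3.04e-15; adjusted p = 0.499 with an estimated correlation), or −0.09 without mice 376 and 184. Oxidative phosphorylation had −0.22 (adjusted p = 1.69e-04; adjusted p = 0.754 with an estimated correlation), or 0.08 without those mice and 0.10 with quantile normalization. Without them the milk lipid (0.04), B cell (0.22) and interferon lists were no longer called, at adjusted p = 0.811, adjusted p = 0.151 and adjusted p = 0.281. Lep, outside these lists, had 0.49 ± 0.17. The size of the epithelial shifts depends on the array of the lowest luminal score of each genotype. Without knock-in 198 luminal epithelium had −0.38, hormone-sensing genes −0.38, basal genes −0.34 and milk genes −0.42, and without wild-type 317 they had −1.15, −1.01, −0.66 and −0.94. The brown and beige (0.26, adjusted p = 0.207) and skeletal muscle lists (0.40, adjusted p = 0.670) were not called without 198. With other single arrays left out, the interferon response call ended without wild-type 256 (−0.18) or 317 (−0.01) or knock-in 196 (−0.25), 314 (−0.21) or 313 (−0.19). The milk lipid synthesis call ended without wild-type 369 (−0.19) or knock-in 196 (−0.20) or 384 (−0.20), and the brown and beige adipocyte call without 313 (0.24). Without mouse 376 growth hormone and IGF genes had −0.10, STAT5 targets −0.12, immediate early genes −0.23 and chaperones −0.19. Without all 3 arrays 6 of the 17 calls ended, those of basal (−0.05, adjusted p = 0.135) and growth hormone genes (−0.08, adjusted p = 0.0847) among them, and with quantile normalization 7 ended or reversed, ribosomal genes (−0.03, adjusted p = 0.832) and chaperones (−0.11, adjusted p = 0.378) among them. Of the 17 lists 11 kept 1 direction in every slide, and so did 22 of 23 genes, all but Egr2. Of 100 splits 9 reached 17 lists, so chance cannot be excluded.

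**Figure D3:**
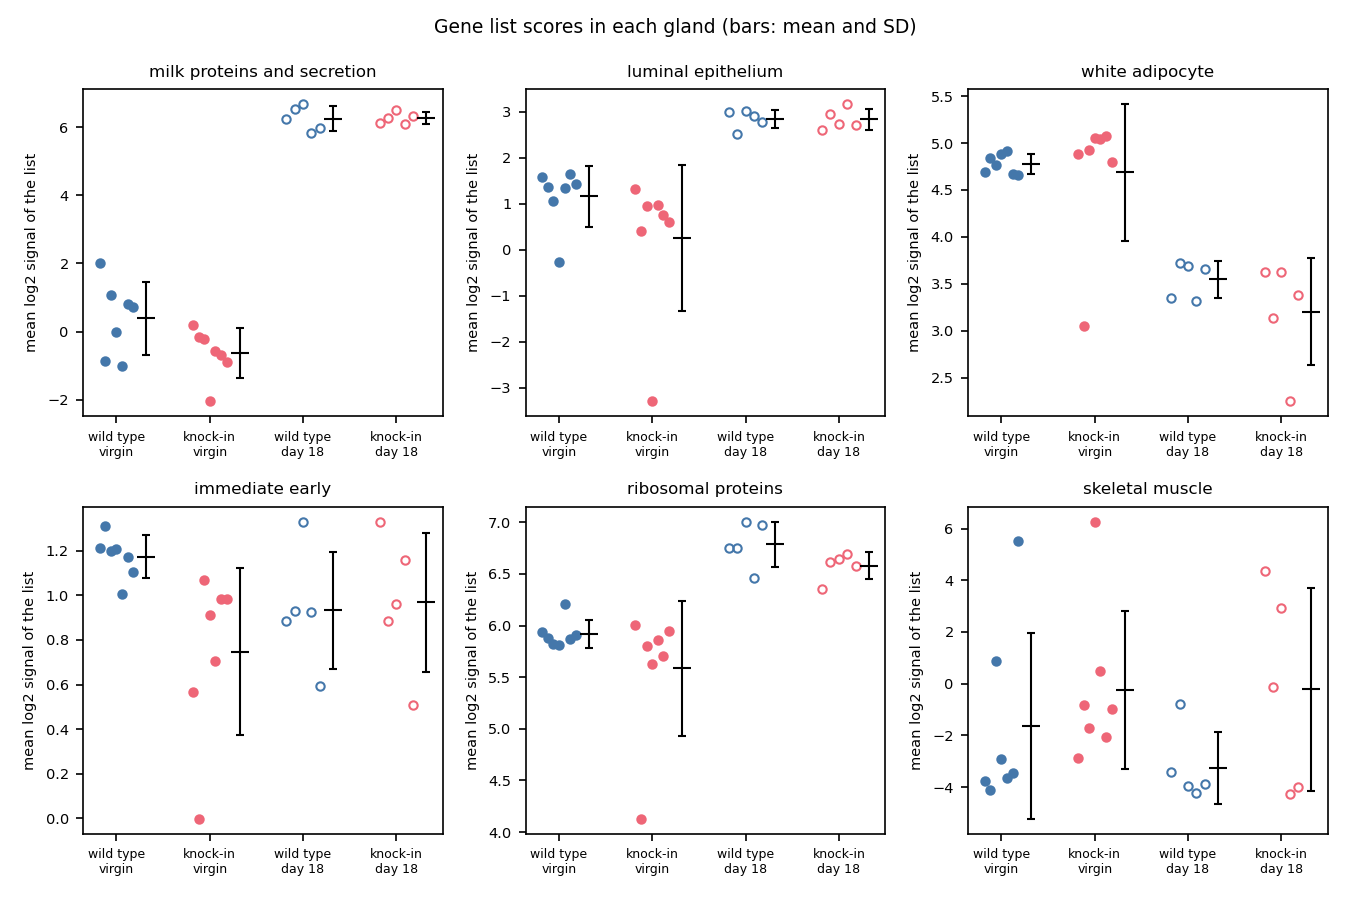
Mean of 6 gene lists on each array, by genotype and stage, as log2 relative to the array's 75th percentile. The lists are milk, luminal epithelium, white adipocyte, immediate early, ribosomal and skeletal muscle.

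Does the allele act at day 18? No gene passed in 5 against 5 mice, all with adjusted p = 1.00, milk genes included: Csn2 had 0.03 ± 1.65 and Cish 0.04 ± 0.53. Among the highest by test were Nrcam, a neuronal adhesion molecule (1.78 ± 0.45), and Dusp15, a phosphatase of myelinating cells (1.58 ± 0.45; 2 of 5 wild-type arrays). Lowest were Acsm3 (−2.40 ± 0.58), Apoc3, an apolipoprotein (−1.28 ± 0.33), and Dpyd, a pyrimidine catabolic enzyme (−0.97 ± 0.25). Gldn, a gliomedin of nodes of Ranvier, was at least 1.27-fold higher, with 0 of 5 wild-type and 2 of 5 knock-in arrays above background.

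By limma 0 genes were called, 441 had an unadjusted p under 0.05 (279 higher), and without the arrays of mice 376 and 184 there were 2 calls, both lower. Of 100 splits 34 reached 441, so chance cannot be excluded. In simulated data 20% of 2-fold and 72% of 4-fold changes were recovered, with noise independent between genes, which can overstate recovery. Median scaling moved the median of all genes by −0.37 and spike-in scaling by 0.10. The shift with median scaling came largely through mouse 184, with a log2 array median of 6.49 against 4.72 to 5.46 on the other day-18 arrays. With slide as a block Nrcam had 1.76, and 1.55, 1.75 and 1.73 within slides, Acsm3 −2.28, then −3.91, −1.49 and −1.36, both at adjusted p = 1.00; 12 of 15 genes kept 1 direction.

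Of 12 lists past the preset test, none passed with an estimated correlation. Nerve and Schwann cell genes had a median of 0.41 (adjusted p = 8.54e-06; adjusted p = 0.224 with an estimated correlation), 0.66, 0.11 and 0.63 within slides, and 3 members were higher when adjusted over the list alone. Inflammatory genes had 0.24, or −0.13 with median scaling (adjusted p = 2.65e-04; adjusted p = 0.224 with an estimated correlation), with Ccl3, a chemokine, at 1.32 ± 0.44 (3 of 5 wild-type arrays). Il6 was below background in 5 of 5 glands of each genotype. Endothelial genes, with Emcn, endomucin, at −0.46 ± 0.25, had −0.31 (adjusted p = 3.70e-06; adjusted p = 0.571 with an estimated correlation). White adipocyte genes had −0.34 (adjusted p = 3.70e-06), milk lipid −0.33 (adjusted p = 1.78e-05), cholesterol −0.20 (adjusted p = 5.76e-04), T cells 0.38 (adjusted p = 9.57e-04) and basal genes −0.23 (adjusted p = 0.0037), each with adjusted p = 0.816 with an estimated correlation. Skeletal muscle had 3.11 (adjusted p = 1.24e-09; adjusted p = 0.816 with an estimated correlation) and −0.15, 3.94 and 8.33 within slides, the first and last with 1 animal in a group, with Tnnc2 at 4.61 ± 2.36 and Myh4 at 5.28 ± 2.82. Cell cycle genes, with Cdk1 at −0.85 ± 0.52, had −0.39 (adjusted p = 1.92e-05), turning direction within slides at 0.52 (adjusted p = 0.0013), −0.49 and −1.18, and ribosomal genes −0.20 (adjusted p = 5.36e-09), each with adjusted p = 0.843 with an estimated correlation, and oxidative phosphorylation −0.22 (adjusted p = 1.22e-07; adjusted p = 0.883 with an estimated correlation). Without knock-in pregnant 239 white adipocyte genes had −0.17 (adjusted p = 0.0705). With quantile normalization 5 of the 12 calls ended: milk lipid (−0.13), cholesterol (−0.13), basal (−0.17), ribosomal (−0.04) and oxidative phosphorylation (−0.06). Without mice 376 and 184 the basal and cell cycle lists stood at adjusted p = 0.124 and adjusted p = 0.0503. Of the 12 lists 8 kept 1 direction in every slide, and 31 of 100 splits reached 12, so chance cannot be excluded. In the milk list (median 0.04, and −0.38, 0.03 and 0.06 within slides), the brown adipocyte, growth hormone, hormone-sensing and immediate early lists, median, mean and test differed in sign.

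Does the effect of the allele differ between stages? Areg had a difference of 5.34 ± 1.31 (5.39 with slide as a block; 5.07, 7.58 and 2.25 within slides), with −3.10 ± 0.85 in virgins. At day 18 it was well above background on 1 of 5 wild-type and 3 of 5 knock-in arrays, so that side of the difference rests on signals near background. Egr2 had 1.61 ± 0.59, Sectm1b −2.49 ± 0.70, Scgb2b20, a secretoglobin, −1.57 ± 0.44, Ttll8, a tubulin glycylase, −1.36 ± 0.36 and Acsm3 −2.56 ± 0.76. All had adjusted p = 1.00. By limma 0 genes were called, 228 had an unadjusted p under 0.05 (104 higher), and 84 of 100 splits reached that number. In simulated data 12% of 2-fold and 72% of 4-fold differences were recovered, with noise independent between genes, which can overstate recovery.

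For the interaction 20 lists passed the preset test, but none with an estimated correlation, where the smallest was adjusted p = 0.203. The highest of the other splits had 19 at the 75th-percentile scaling with all arrays. A margin of 1 list is too small to exclude chance, since several counts were compared in this way. The margin is gone with slide as a random block, which gave 19. The count was 20 with spike-in scaling, 19 with normexp correction, 17 with quantile normalization, 13 with median scaling, 11 with luminal and muscle scores as covariates, 16 to 20 with 1 array left out, 16 without mice 376 and 184 and 2, 15 and 14 within slides, and splits were not run under any of these settings. Skeletal muscle had 1.60 (adjusted p = 0.0075), but −2.01 (adjusted p = 2.65e-10), −1.04 and 9.76 within slides, so its direction rests on slide 3 with 1 knock-in day-18 array, from mouse 211, and the skeletal muscle call ended when 1 mouse was left out: 211 (0.27), 184 (0.62), 256 (1.06), 320 (0.28), 196 (0.96), 314 (1.39) or 313 (1.32). Next were milk, 0.86 (adjusted p = 1.15e-05, and adjusted p = 0.267 with an estimated correlation), and luminal epithelium, 0.81 (adjusted p = 2.28e-07, and adjusted p = 0.577 with an estimated correlation). On the virgin side the shifts of both lists were smaller without knock-in 198. Immediate early genes had 0.41 (adjusted p = 2.19e-05), STAT5 targets 0.35 (adjusted p = 4.56e-04) and nerve genes 0.48 (adjusted p = 5.74e-04), each with adjusted p = 0.267 with an estimated correlation. Hormone-sensing genes had 0.48 (adjusted p = 6.73e-04; adjusted p = 0.432 with an estimated correlation), inflammatory genes 0.49 (adjusted p = 5.78e-05; adjusted p = 0.203 with an estimated correlation) and white adipocyte genes −0.25 (adjusted p = 4.56e-04; adjusted p = 0.704 with an estimated correlation), a call that ended without mouse 239 (−0.02). Of the 20, 13 kept 1 direction in every slide. With quantile normalization the T cell (0.02), cell cycle (0.09) and ribosomal (−0.01) medians changed sign.

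Averaged over stages, is there a common effect? By limma 0 genes were called and 1160 had an unadjusted p under 0.05 (678 higher), all named here with adjusted p = 0.651. Kng1 had 1.18 ± 0.26, Col6a5, a collagen VI chain, 1.01 ± 0.28 and Ly6h 0.47 ± 0.13. Sostdc1 had −0.87 ± 0.18, Lamc3, a laminin chain, −0.64 ± 0.13 and Ston2, an endocytic adaptor, −1.28 ± 0.28. With slide as a block Kng1 and Sostdc1 stood at adjusted p = 0.587 and the other 4 at adjusted p = 0.821. Without mice 376 and 184 Lamc3 and Ston2 had adjusted p = 0.0571. Of 100 splits 12 reached 1160, so chance cannot be excluded, and median scaling moved the median of all genes by −0.38.

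For this average 19 lists passed the preset test and none with an estimated correlation (smallest adjusted p = 0.502), and 5 of 100 splits reached 19. Ribosomal genes had −0.28 (adjusted p = 1.39e-16), luminal epithelium −0.46 (adjusted p = 1.14e-04), basal genes −0.31 (adjusted p = 5.34e-05), milk lipid −0.30 (adjusted p = 1.14e-04), T cells 0.33, or −0.06 with median scaling (adjusted p = 3.41e-07), and skeletal muscle 2.27 (adjusted p = 9.25e-08). With quantile normalization 11 of the 19 calls ended or reversed, among them ribosomal genes (−0.04, adjusted p = 0.581), milk lipid (−0.11, adjusted p = 0.890) and basal genes (−0.28, adjusted p = 0.0937). Without mice 376, 184 and 198 luminal epithelium had −0.12 (adjusted p = 0.111), and without wild-type virgin 317 it had −0.61. Of the 19 lists 12 kept 1 direction in every slide.

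Do the effects of the allele resemble each other at the 2 stages? Across genes, which are not independent replicates, the virgin and day-18 differences had a Pearson correlation of 0.473 and a Spearman correlation of 0.461, and 68.2% of genes had the same sign. At each stage 0 genes were called, so no gene was shared. Without mice 376 and 184 the correlations were 0.133 and 0.071, and with slide as a block 0.429 and 0.379. Regardless of sign, 8 of 100 splits, the real one included, reached 0.473, the largest other being −0.577, so chance cannot be excluded by that count. With a positive sign only the other splits at 0.491, 0.489 and 0.488 did.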

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

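The tests of the 2 distal Socs2 probes, and the tests of the immediate early, luminal and milk lists without single arrays, were chosen after the results were seen; the tests with slide or the luminal score and the regrouping of animals were not.

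Both distal Socs2 probes read higher in knock-in glands, by 1.60 and 1.78 averaged over stages, and their mean difference was 1.69 ± 0.23. High-background arrays or slide do not account for it: without mice 376 and 184 and with slide as a block it was 1.73 (95% interval 1.19 to 2.27). A rise of the whole transcript does not either, since the other 2 probes differed by −0.33 (−0.93 to 0.29). Sequence carried with the knock-in allele, such as a changed transcript end or remaining vector sequence, is a candidate explanation that stays open: the neighbouring genes had a median of −0.11, but allele and genotype belong to the same animals. Sequencing across the Socs2 locus, or RNA reads spanning the exons, would test that explanation.

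Immediate early genes were lower in knock-in virgins, by −0.43 in list score. Mice 376 and 198, of high background and of little epithelium, do not account for all of it, since without them the difference was −0.31 (exact p = 0.0025; −0.51 to −0.11). Less epithelium does not either, at −0.46 with the luminal score as a covariate (−0.82 to −0.10), nor does slide, at −0.41 as a block (−0.76 to −0.06), though within slides it was −0.72, −0.40 and −0.11. The scanner software also marked knock-in virgins 196, 251 and 314, with 1 quality metric out of range each, and no wild-type virgin. Their list scores were 0.566, 0.707 and 1.070, against 0.913, 0.985 and 0.986 in unmarked knock-in 198, 313 and 384. Wild-type virgins had 1.006 to 1.310. Array quality beyond mouse 376 was therefore not separated from genotype. A difference in handling time before freezing might also lower immediate early genes and could not be tested with the labels. Whether the allele lowers stimulation of the virgin gland stays open too, and glands frozen after recorded intervals would separate it from handling.

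Luminal and milk lists differed in knock-in virgins by −0.92 (exact p = 0.149) and −1.02 (exact p = 0.0618) in list score, and with an estimated correlation stood at adjusted p = 0.412 and adjusted p = 0.330. Without mouse 376 and the lowest luminal array of each genotype, 198 and 317, the luminal difference was −0.48 (exact p = 0.0130; −0.81 to −0.16), but arrays picked by this score lower its spread, so the luminal list stays open between such arrays and genotype. The milk difference was then −0.89 (exact p = 0.143; −2.14 to 0.36), and −0.65 (−1.68 to 0.39) with the luminal score as a covariate. Those 2 intervals include both 0 and the full difference, so the milk list stays open between gland makeup and genotype. Counting epithelium in sections of the same glands would decide it.

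Regrouping the animals in 100 ways, the real one included, gave at least as many genes as the real grouping in 62 cases for the virgin comparison (802 genes, highest other 2476), 34 at day 18 (441, 2557), 84 for the difference (228, 2434) and 12 for the average (1160, 3047), so chance cannot be excluded there. It can be for the stage counts, 1 case each: 9357 against at most 15 in wild-type and 9658 against at most 2503 in knock-in mice, the latter from a split that largely exchanged the stages (2 of 12 knock-in arrays kept theirs). For lists the cases were 9 in virgins (17 lists, highest other 19), 31 at day 18 (12, 17), 5 for the average (19, 22), 31 for stage in wild-type (15, 18) and 16 in knock-in mice (16, 20), and chance cannot be excluded for these counts. The median over the splits was 12 lists for stage in either genotype. With so many lists passing in other groupings, the list count could hardly separate the stages, although the gene counts did. For the difference of genotype effects there was 1 case (20, 19) at the 75th-percentile scaling. A margin of 1 list is too small to exclude chance, since several counts were compared in this way. With slide as a random block the count was 19, equal to the highest other. It was 20 with spike-in scaling, 17 with quantile normalization, 13 with median scaling, 11 with covariates, 16 to 20 with 1 array left out and 16 without mice 376 and 184. No splits were run under these settings. For the correlation of 0.473 there were 8 cases regardless of sign (largest other −0.577, and 0.491 among positive ones).

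The 20 lists whose genotype effect differed between stages by the preset test had medians of 0.86 for milk, −0.16 for cholesterol, −0.25 for white adipocyte, −0.29 for brown and beige adipocyte, 0.35 for STAT5 targets, 0.21 for growth hormone and IGF, 0.48 for hormone-sensing, 0.81 for luminal, −0.13 for endothelium and −0.12 for T cells. For macrophage it was 0.15, interferon 0.52, inflammatory 0.49, immediate early 0.41, cell cycle −0.11, chaperones 0.20, skeletal muscle 1.60, nerve 0.48, red blood cells 0.55 and ribosomal 0.15. The direction turned for ribosomal genes (−0.10 without mouse 376, −0.01 with quantile normalization), cell cycle (1.14 in slide 2), T cells (0.34 in slide 3) and muscle (−2.01 in slide 1), among others. None of the 20 passed with an estimated correlation, the smallest being adjusted p = 0.203.

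A search for single outlying arrays covered 98 genes and 32 lists in 4 groups, 536 sets of values including probes, and found 72; chance gives about 1 in 20 sets. Values here are the gap to the nearest array of the group as a share of the group's range. Over all 389 genes of the naming rule it found 233 in 1556 sets, 99 of them in knock-in virgin 376, 23 in 198, 21 in wild-type virgin 317 and 13 in knock-in pregnant 184.

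Knock-in virgin 376 stood apart in 25 sets. It was lowest in the white adipocyte (0.866), growth hormone and IGF (0.638), fibroblast (0.696), endothelium (0.629), substrain (0.912), ribosomal (0.800) and oxidative phosphorylation (0.633) lists and highest in the skin list (0.876). It was lowest in Plin1 (0.71), Adipoq (0.874), Igf1 (0.613), Esr1 (0.694), Fn1 (0.659), Vwf (0.683), Rpl22l1 (0.788), Jak2 (0.899), Acsm3 (0.586), Sik1 (0.692) and Emcn (0.661). It was highest in Olah (0.663), Sycn (0.640), Drd4 (0.699), Saa1 (0.749), Ttll8 (0.603) and Scgb2b20 (0.631).

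Knock-in virgin 198 was lowest in the luminal list (0.804), Dmbt1 (0.690), Ido1 (0.664), Cyp3a57 (0.825), R3hdml (0.655), Lalba (0.617), Elf5 (0.783), Esrp1 (0.659) and Krt18 (0.680), and highest in the muscle list (0.631). Wild-type virgin 317 was lowest in the luminal list (0.696), Dmbt1 (0.678), Ido1 (0.669), Abcc8 (0.631), R3hdml (0.729), Elf5 (0.579), Krt18 (0.665) and Krt14 (0.71). Knock-in pregnant 184 was highest in the brown and beige list (0.843), Ido1 (0.816), Fam25c (0.891), Cyp3a57 (0.757), R3hdml (0.827) and Fgb (0.857).

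Wild-type pregnant 235 stood apart in Ghr (0.872), Lep (0.747), Nrcam (0.826) and Emcn (0.763), knock-in pregnant 239 in Saa2 (0.834), Cd14 (0.745) and Saa1 (0.898), and wild-type pregnant 232 in Dmbt1 (0.842), R3hdml (0.772) and Il6 (0.794). Wild-type pregnant 233 did in the muscle list (0.756), the brighter reference Socs2 probe (0.759) and Cited4 (0.788), and wild-type pregnant 234 in the fibroblast list (0.757). In wild-type virgins they were 188 in chaperones (0.652) and Atp13a4 (0.737), 365 in Prox1 (0.572) and Gjb6 (0.793), and 369 in ribosomal genes (0.685) and Fn1 (0.586). Knock-in virgin 196 stood apart in Cdk1 (0.588), and knock-in pregnant 210 in Prox1 (0.735) and 211 in Chrdl2 (0.811).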

How the results depend on the processing

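Of the alternatives, 3 were added after the results were seen: leaving out mice 376 and 184, leaving out those and mouse 198, and luminal and muscle scores as covariates. The stage effects had at least 4306 calls under every setting but slides 1 and 3 alone, which have 1 wild-type and 1 knock-in pregnant array, and the genotype comparisons, each with 0 calls, reached at most 21. A list counts here as reversed when its test turned direction while past the threshold under either setting, so its median, the value given, can keep its sign; values past the threshold under neither count as unchanged even where the sign differs. Named genes kept direction and side of the threshold in 2588 values for stage in wild-type mice (75 weaker, 18 stronger, 2 reversed), 1327 in knock-in mice (28 weaker, 1 reversed), 977 in virgins (4 stronger), 636 at day 18, 297 for the difference and 297 for the average (4 stronger). Lists did in 1239 in virgins (57 weaker, 46 stronger, 32 reversed), 1299 at day 18 (20, 47, 8), 1154 for the difference (160, 40, 20), 1250 for the average (46, 53, 25), 1326 for stage in wild-type (25, 21, 2) and 1317 in knock-in mice (34, 16, 7). Over all 905 entries of the naming rule 649 values were not unchanged, 17 of them reversed. The cause was not tested for any value that follows, except that single slides and smaller sets of arrays or probes hold fewer values. Calls in virgins became 1 in slide 2, 21 with array weights (8 higher, 13 lower) and 1 without 3 arrays; at day 18, 2 with median signal, 2 without 2 arrays and 1 without 3; for the difference, 1 in slide 2; for the average, 1 each with median scaling, median signal, slide 2, array weights and without 3 arrays, and 2 with every probe tested. Stage calls in wild-type mice became 5316 with median scaling (2834 higher, 2482 lower), 14807 with spike-in scaling (1142, 13665), 56 in slide 1 (29, 27), 5601 in slide 2 (2907, 2694), 14071 with array weights (7297, 6774) and 6088 with a 2-fold limit (2671, 3417). In knock-in mice they became 5068 with median scaling (2710, 2358), 715 in slide 1 (333, 382), 6208 in slide 2 (3644, 2564), 3241 in slide 3 (1506, 1735), 4306 with covariates (2031, 2275) and 6145 with a 2-fold limit (2840, 3305). Of 86 gene-by-comparison entries of named genes past the threshold, 43 were past it with probes bright on all arrays, where the others were not measured and 0 became weaker. In slide 1, 28 were past it. The correlation of genotype effects across genes was 0.106 in slide 1, −0.124 in slide 3, 0.098 with array weights, 0.172 without mouse 376, 0.133 without 2 arrays and 0.058 without 3. Leaving out 1 array at a time left 0 calls in each genotype comparison. Stage calls were 8202 (wild-type pregnant 206) to 12822 (knock-in virgin 376) in wild-type and 8374 (knock-in pregnant 239) to 12367 (376) in knock-in mice. List calls over the 6 comparisons together were 94 (376) to 106 (wild-type virgin 188). Gene-by-comparison entries past the threshold were 86 to 88, and correlations 0.172 (376) to 0.531 (239). With quantile normalization reversed list medians in virgins were 0.00 for milk lipid (adjusted p = 0.223), 0.10 for white adipocyte (adjusted p = 1.37e-04), 0.14 for fibroblast (adjusted p = 0.0015) and 0.10 for oxidative phosphorylation (adjusted p = 2.18e-09); for the difference −0.01 for ribosomal (adjusted p = 0.721); for the average −0.043 for white adipocyte (adjusted p = 0.919), 0.056 for fibroblast (adjusted p = 0.0225), 0.089 for macrophage (adjusted p = 0.0191), −0.054 for chaperones (adjusted p = 0.962), −0.053 for glucose (adjusted p = 0.562) and 0.015 for oxidative phosphorylation (adjusted p = 7.95e-04); for stage −0.49 and −0.61 for oxidative phosphorylation in wild-type and knock-in mice. With median signal they were −0.00 for milk lipid, 0.083 for white adipocyte, 0.13 for fibroblast and 0.11 for oxidative phosphorylation in virgins, 0.084 for milk at day 18, 0.009 for ribosomal in the difference, 0.043 for fibroblast, 0.092 for macrophage, −0.070 for chaperones, −0.042 for glucose and 0.025 for oxidative phosphorylation in the average, and −0.49 and −0.61 for oxidative phosphorylation by stage. Scaled to the spike-ins, stage values reversed for Socs3 (−0.86) and Lep (−0.79) in wild-type mice and for the muscle list (−0.84) in knock-in mice. In slide 1 the cell cycle list had 1.03 in virgins, 0.52 at day 18 and 0.74 in the average, the inflammatory list −0.057 and the muscle list −0.15 at day 18, and for the difference cholesterol had 0.16, growth hormone 0.028 and muscle −2.01. In slide 2 virgin values were 0.57 for milk lipid, 0.48 for cholesterol, 0.15 for white adipocyte, 0.50 for glucose and 0.46 for oxidative phosphorylation; the difference gave 1.14 for cell cycle, −0.53 for glucose, −1.04 for muscle and −0.056 for ribosomal; the average gave 0.14 for cholesterol, −0.009 for white adipocyte, 0.14 for glucose, 0.071 for nerve and 0.13 for oxidative phosphorylation, which had −0.30 by stage in knock-in mice. In slide 3 virgin values were −0.009 for milk lipid, 0.21 for white adipocyte, −0.066 for T cells, 0.062 for interferon, −0.005 for chaperones, −0.97 for muscle and 0.065 for oxidative phosphorylation. Day 18 there gave 0.062 for milk, −0.12 for milk lipid, 0.11 for white adipocyte and 0.33 for immediate early; the difference gave −0.008 for white adipocyte, 0.34 for T cells, 0.57 for neutrophil and −0.22 for ribosomal. The average in slide 3 gave −0.044 for milk lipid, 0.16 for white adipocyte, 0.27 for macrophage, 0.25 for interferon, 0.16 for immediate early, −0.063 for chaperones and −0.083 for skin, and stage in knock-in mice 6.28 for muscle and −0.47 for oxidative phosphorylation. With array weights virgin values were 0.20 for milk lipid, 0.18 for white adipocyte, −0.019 for interferon and 0.12 for oxidative phosphorylation, the difference −0.085 for ribosomal, the average 0.006 for glucose and stage in knock-in mice −0.23 for oxidative phosphorylation. With 1 array left out, the interferon list ranged in virgins from −0.42 (without knock-in virgin 251) to −0.010 (without wild-type virgin 317), white adipocyte from −0.21 (without 198) to 0.15 (without 376) and oxidative phosphorylation from −0.33 (without 313) to 0.080 (without 376). For the difference, cell cycle ranged from −0.39 (without wild-type virgin 317) to 0.10 (without knock-in virgin 196) and ribosomal from −0.10 (without 376) to 0.23 (without 196). Without mice 376 and 184, virgins had 0.15 for white adipocyte and 0.080 for oxidative phosphorylation, and the difference −0.10 for ribosomal. Without 3 arrays they were 0.11 for white adipocyte, 0.17 for muscle and −0.14 for ribosomal. With covariates Krt14 had −0.70 by stage in knock-in mice, and for the difference the basal list had −0.22 and the cell cycle list 0.077.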

Other observations

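The tests of the milk share were chosen after the results were seen. The share of the summed array signal that came from probes of the 30 milk genes was 0.20 ± 0.04% (SD) in wild-type virgins, 0.17 ± 0.03% in knock-in virgins, 1.64 ± 0.14% in wild-type and 1.93 ± 0.13% in knock-in glands at day 18. At day 18 the 5 knock-in glands had 1.74 to 2.07% and the 5 wild-type glands 1.44 to 1.77%, a difference of 0.290 (exact p = 0.0159 over 252 splits), or 0.255 without mouse 184 (exact p = 0.0238). In virgins the difference was −0.029 (exact p = 0.122), or −0.024 without mouse 376 (exact p = 0.230). The share follows the brightest milk genes, while the mean log2 score of the list at day 18 was 6.25 ± 0.36 in wild-type and 6.27 ± 0.17 in knock-in glands (exact p = 0.913).

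Muscle genes varied between single glands in all groups: the skeletal muscle score was 5.52 in wild-type virgin 320, 6.27 in knock-in virgin 198, 4.37 in knock-in pregnant 211 and 2.94 in knock-in pregnant 184. At day 18 it averaged −3.26 ± 1.41 (SD) in wild-type and −0.23 ± 3.94 in knock-in glands (exact p = 0.183).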
